A study of Mus musculus with 6 samples.

How the data were processed

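RNA from 6 splenocyte libraries, 3 per group, was analysed from 2 tables deposited for the whole series. The deposited count table holds whole-number exon read counts per gene symbol, not normalized, with 1 column per library. In the deposited normalized table the values are a signal: gene counts divided by 1 size factor per library by the authors. Per the submitters' processing notes, STAR 2.7.2d, DESeq2 1.28.1 and the genome build mm10 were used, and their roles, the counting tool, the annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes cannot be told apart. Of 150 genes named by rule, 149 have a gene model in GENCODE M21 on GRCm38, the assembly also called mm10. Of these, 20 overlap the span of another tested gene there, introns included. Reads of genes with near-identical copies (histones, ribosomal proteins, granzymes, NK cell receptors, globins and the Ifit family) can map to more than 1 copy, and how such reads were counted is not given either, so these values are uncertain. The 92 spike-in rows held 0 counts in all libraries and were left out. In 27 rows the symbol reads as a calendar date, and 4 of these share a symbol with another row. They were tested and are not named.

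Columns were assigned to samples by their titles alone. The check of the 2 tables against each other showed that each normalized column is a constant multiple of the count column with the other group's title and the same replicate number (6 of 6 columns, and 0 match their own title). Size factors computed with DESeq2 from the count table differed from those in the normalized table by at most 3.54e-06 in relative terms. Dividing each normalized column by the value of 1 read gave whole reads for 100% of values above 0 at a tolerance of 0.1 reads, and edgeR on those reads, grouped by the normalized table's own header, called 3726 genes higher and 3584 lower. The comparisons follow the count table's header, as the design was fixed before the data were examined, and whether that header or the other is right could not be settled from the sources used here.

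Total counts per library ran from 17166687 to 25789381 over 23453 gene rows, and this depth limits precision for genes with few counts. Genes were kept with edgeR's filterByExpr, scaled with TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with the group as the sole term and Benjamini-Hochberg adjustment over 12423 genes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are scaled by TMM and given as mean ± SD. Replicates of 1 group differed by more than sampling noise (chi-square per gene 5.08 to 110 in pairs of libraries), so no library was counted as a duplicate. Pairs that held replicate 1 gave 62.0 to 110, while replicates 2 and 3 gave 5.08 in FCM and 7.48 in TCM. Replicates 2 and 3 of each group were thus far closer to each other than to replicate 1. Ratios with 3 counts in 1 group carry an exact binomial interval at 95% that covers counting error only.

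Gene lists were fixed beforehand from general knowledge of T cells and splenocyte cultures. Of 48 lists, 46 had at least 5 tested genes. Camera (limma 3.58.1) tested each against all other genes on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 46 lists. With the correlation estimated per list, none of the 20 calls held. Estimates lay below 0.01 for p53 targets (-0.016), glycolysis (-0.047), fatty acid oxidation (-0.029) and metal response (-0.059). The same held for erythroid and platelet (-0.062) and NK cell markers (-0.058), and the other called lists lay above 0.01. A higher correlation is therefore not why the lists below 0.01 lost their calls. At an estimate near 0.01, camera's unadjusted p rose from 0.00355 to 0.0477 for the unfolded protein response (0.013). For B cell markers (0.012) it rose from 0.00605 to 0.0536. A call lost with an estimated correlation thus does not by itself show that correlated genes had made the call. The estimated setting was not tried on the simulated counts. For lists that were not called, the values given over settings are the lowest and highest median over the settings with the count table's header. Ranges and counts over settings leave out the removal of a trend on GC content and any trend removal run together with the replicate block. Members were counted over all genes and adjusted over the list alone. Fry, which asks whether the genes of a list move one way on balance, was run as an alternative. The text names by rule the 6 largest rises and 6 largest falls with adjusted p under 0.05, mean log2 CPM of at least 3 and no overlap between groups, leaving out unnamed models. It also names the 3 members with the smallest p in each list that camera called or that had at least 2 called members, and at most 1 in other lists. Gzmb, Prf1, Ifng, Tnf, Il2, Pdcd1, Tcf7, Cd8a and Myc are named whatever their values. Some genes that the rule takes are not reported here. Other genes, such as the exceptions within a list, were chosen after their values were seen.

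The labels give both groups the replicate numbers 1 to 3 without saying what a number marks. Deviations from the group means correlated at 0.60, 0.15 and 0.36 across genes for the same numbers, each over 0.1, so the numbers were taken to pair the libraries, from the data and not from the labels. FCM replicate 2 correlated better with TCM replicate 3 (0.42), and TCM replicate 2 with FCM replicate 3 (0.27). The values thus set replicate 1 apart and do not settle a pairing of numbers 2 and 3, and the main fit has no replicate term. With the replicate block, 4509 genes were higher and 4594 lower in the count-table TCM libraries, and 20 lists were called.

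The scripts were tested on simulated counts with 200 changed genes drawn from the real means, depths and dispersions. Over 12291 genes, 82% of genes changed 2-fold and 97% of those changed 4-fold were recovered, and 15 of 194 calls were unchanged genes. A list shifted 1.5-fold was the 1 list called of 46. Genes were drawn independently there and all genes outside the shifted list were unchanged. In the real data the estimated correlation reached 0.48 (T cell cytokines and chemokines) and many genes changed. The simulation therefore does not measure false list calls in the real data. For genes, 58.8% of those tested passed in the real data, and the simulated counts did not set replicate 1 apart. The rates of recovered genes and of unchanged genes called thus hold for the simulated setting only. A simulated slope of -0.30 on log2 transcript length was brought to -0.008 by the removal of the length trend.

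Alternatives listed beforehand were DESeq2's size factors in edgeR, library totals alone, no filter on low counts, a minimum of 50 counts in every library of 1 group, DESeq2 1.42.0 as the test, the replicate block, each library left out in turn, an estimated correlation per list and fry. Added after seeing the data were the libraries without replicate number 1, the table without Rn45s, the removal of a trend on transcript length (loess, span 0.5, on the longest GENCODE M21 transcript of each gene) and the reads and header of the normalized table. Tables were prepared and plotted with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.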

Results

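Gene expression was measured by RNA sequencing in splenocyte cultures from OT1 mice, whose T cells carry a transgenic receptor for an OVA peptide, on the C57BL/6 strain. The cultures received the OVA peptide for 48 h and then either FCM or TCM for 8 h, and the labels give cytotoxic T lymphocytes as the cell type. The labels do not expand FCM or TCM, and the samples that received FCM are titled vehicle. Each group had 3 libraries. The totals of the count table were 18729982, 25789381 and 25027125 counts for FCM replicates 1 to 3 and 17166687, 17684319 and 21197117 counts for TCM replicates 1 to 3. A single count was therefore worth 0.0388 to 0.0583 CPM, the usual scaling of counts to the library total, before the scaling by TMM. The ribosomal RNA row Rn45s took between 11.2% and 18.9% of each library.

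The titles of the 2 deposited tables contradict each other. Each of the 6 columns of the normalized table was a constant multiple of 1 column of the count table, and in 6 of 6 cases that column carried the other group's title with the same replicate number. The coefficient of variation of the ratio over genes was at most 1.79e-10 in the matched pairs and at least 2.60 between columns of one title. Both tables therefore hold the same libraries in the same groups of 3 and differ in which group is called TCM. All directions are given by the count table's header, as "count-table TCM" against "count-table FCM", and each of them reverses under the header of the normalized table. No label says whether replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

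The comparison asked how 8 h in TCM differed from 8 h in FCM after peptide stimulation. By the count table's header, and among genes with a mean log2 CPM of at least 3 and no overlap between the groups, the largest rises included transcripts of Cxcl3, a neutrophil-attracting chemokine, Il10, an immunoregulatory cytokine, and Phlda3, a p53 target. Under the same limits, the largest falls were in granule and antimicrobial genes of neutrophils and other myeloid cells, Ltf (lactoferrin), Ngp, Pglyrp1 and Camp (cathelicidin), together with Slfn4 and Abca13. Ngp had 3553 ± 921 CPM (SD, n = 3) in the count-table FCM libraries and 84.8 ± 12.3 CPM in the count-table TCM libraries, a 41.9-fold fall. Ltf went from 125 ± 15.0 to 0.824 ± 0.207 CPM, a 153-fold fall, and Camp from 640 ± 157 to 22.0 ± 7.86 CPM, a 29.1-fold fall. Il10 rose 26.7-fold from 3.0 ± 0.309 to 80.0 ± 12.2 CPM and Cxcl3 rose 38.7-fold from 3.88 ± 0.869 to 151 ± 28.2 CPM.

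Of 12423 genes tested with edgeR's quasi-likelihood test, 7310 (58.8%) passed an adjusted p of 0.05 (Benjamini-Hochberg), with 3584 higher and 3726 lower in the count-table TCM libraries. At least 2-fold changes numbered 1631 upward and 1308 downward, and 7911 genes had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap in 64.2% of genes, where chance gives 10%. The common biological coefficient of variation was 15.3%. The first principal component held 86.4% of the variance and separated the groups, and the second held 8.32% and set the replicate 1 libraries of both groups apart from the rest. With library totals alone as scaling, the median fold change of all genes moved by -0.21 on the log2 scale and the calls became 2364 higher and 3965 lower, so that 37.4% of the calls were higher against 49.0% with TMM.

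The genes with the largest changes, at a mean log2 CPM of at least 3 and with no overlap between the groups, were protein-coding in GENCODE M21 on GRCm38. On the log2 scale with standard errors, Sgip1 (chromosome 4, 102741297 to 102973628) rose by 6.11 ± 0.24 and Crip2 (chromosome 12, 113140236 to 113145506) by 5.54 ± 0.19. Cxcl3 (chromosome 5, 90786103 to 90789600) rose by 5.28 ± 0.23, and Ppp1r13l (chromosome 7, 19359749 to 19378533), which encodes an inhibitor of p53, by 4.74 ± 0.19. Il10 and Phlda3 lie on chromosome 1 (131019845 to 131024974 and 135766119 to 135769136) and rose by 4.74 ± 0.17 and 4.49 ± 0.26. Ltf, Ngp and Camp lie on chromosome 9 (111019271 to 111042767, 110419747 to 110423012 and 109847379 to 109849617) and changed by -7.26 ± 0.21, -5.39 ± 0.29 and -4.86 ± 0.33. Slfn4 (chromosome 11, 83175186 to 83190216) changed by -5.01 ± 0.16 and Pglyrp1 (chromosome 7, 18871331 to 18890459) by -5.05 ± 0.26. Abca13 (chromosome 11, 9191942 to 9684259) changed by -4.33 ± 0.14. Adjusted p-values of edgeR's test for these 12 genes lay between 3.35e-07 and 5.67e-06, and none of the 12 overlapped another tested gene. The normalized table's header turns each of these directions around.

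**Figure D1:**
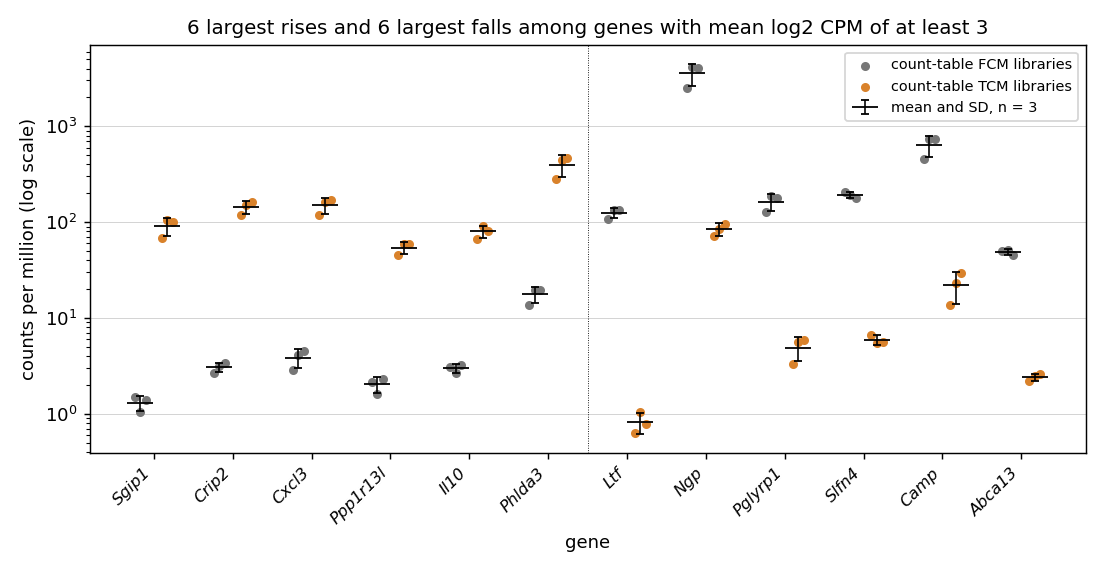
CPM (log scale) of the 12 genes named for the largest changes, per library, with mean and SD (n = 3) in the count-table FCM and count-table TCM libraries. Ngp had 3553 ± 921 CPM in the count-table FCM and 84.8 ± 12.3 CPM in the count-table TCM libraries, and for none of the 12 genes did the groups overlap; the normalized table's header exchanges the group names.

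Among T cell effector genes, Gzmb, the cytotoxic granule protease granzyme B, rose 5.86-fold from 488 ± 39.9 to 2859 ± 309 CPM (SD, n = 3; adjusted p = 9.91e-06, edgeR). Ifng rose 2.49-fold to 2012 ± 395 CPM, while Prf1, which encodes the pore-forming protein perforin, fell 1.40-fold to 20.3 ± 0.768 CPM. Tnf fell 1.61-fold, Il2 2.25-fold, Pdcd1, the gene of the inhibitory receptor PD-1, 1.60-fold, Cd8a 1.59-fold and Myc 1.55-fold. Tcf7, a transcription factor gene of naive and memory T cells, did not pass the test, with a log2 change of -0.18 ± 0.13 (SE; adjusted p = 0.261, edgeR). Without the replicate 1 libraries of both groups, a setting chosen after seeing the data, it passed at -0.27 (adjusted p = 0.00394 in edgeR), and over all settings its log2 change ran from -0.38 to -0.14 and its adjusted p from 0.00394 to 0.51. In the CTL effector list 8 of 17 tested genes rose, 4 fell and 5 did not pass, with equal counts adjusted over the list alone. Serpinb6b and Serpinb9, inhibitors of granule proteases, rose by 1.58 and 1.49 on the log2 scale beside Gzmb, and the list as a whole did not pass camera (median 0.32, 0.032 to 0.58 over settings, adjusted p = 0.172). Its median was 0.58 without TCM replicate 1 and 0.032 with the transcript length trend removed. All of these directions follow the count table's header and reverse under the other.

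T cell cytokines moved in both directions. In that list 7 of 22 genes rose and 11 fell, with equal counts adjusted over the list alone (median -0.37, -0.74 to -0.31 over settings, camera adjusted p = 0.464). With the length trend removed the list passed at a median of -0.74 and an adjusted p of 0.0251 (up to 0.807 over the settings at the preset correlation), and with an estimated correlation, the trend left in, it had an adjusted p = 0.875. Il21 rose 7.63-fold, and the chemokine gene Ccl1 had 3 counts over the count-table TCM libraries against 991 over the count-table FCM libraries, a ratio of 230 (95% exact counting interval 78.4 to 1116). Of 22 genes linked to inhibitory receptors and exhaustion, 4 rose and 11 fell, with equal counts adjusted over the list alone (median -0.55, -0.75 to -0.32 over settings, adjusted p = 0.0972). Rgs16, a regulator of G protein signalling, fell 16.5-fold and Eomes 2.60-fold, whereas Ctla4 rose 8.07-fold. In the naive and memory list 7 of 18 genes rose and 5 fell, again equal over the list alone, and its median (-0.013, -0.21 to 0.24 over settings) differed in sign from its mean (0.27) and its test, which gave an upward direction (adjusted p = 0.707). Dapl1, Lef1 and Igfbp4 rose by 4.37, 1.52 and 2.03 on the log2 scale. Of 24 early activation genes 9 rose and 5 fell, equal over the list alone (median 0.23, -0.0025 to 0.32 over settings, adjusted p = 0.243), and Egr3 and Tnfrsf18 rose 3.78-fold and 4.14-fold while Spry2 fell 2.61-fold. These directions hold for the count table's header and reverse with the other.

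Interferon-stimulated genes were lower in the count-table TCM libraries as a group. Of 40 genes tested 37 fell, 1 rose (Bst2) and 2 did not pass (Mx2 and Socs1), with equal counts adjusted over the list alone (median -1.71, camera adjusted p = 2.50e-14, and adjusted p = 0.0775 with an estimated correlation). Ifit3 fell 32.3-fold from 30.1 ± 3.06 to 0.928 ± 0.135 CPM (SD, n = 3), and the antiviral synthetase genes Oas2 and Oasl2 fell 9.20-fold and 10.1-fold. The call is camera's at the preset correlation of 0.01, and its direction reverses under the normalized table's header. The neutrophil marker list moved the same way in the same libraries, with a median of -3.76.

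The integrated stress response, aminoacyl-tRNA synthetase, amino acid transport and unfolded protein response lists were each called lower in the count-table TCM libraries by camera at the preset correlation, and none kept its call with an estimated correlation. In the integrated stress response list 22 of 30 genes fell and 5 rose (23 and 5 adjusted over the list alone, median -1.12, camera adjusted p = 7.04e-05, and adjusted p = 0.208 with an estimated correlation). Aldh1l2, a mitochondrial folate enzyme, fell 20.4-fold, Cth, which makes cysteine, 7.60-fold, and the asparagine synthetase gene Asns 3.96-fold from 47.9 ± 2.28 to 12.1 ± 0.938 CPM (SD, n = 3). The 5 that rose were Cbs, Ddit4, Slc7a11, Atf3 and Sesn2. Of 20 aminoacyl-tRNA synthetase genes 15 fell and 1 rose (Dars), equal over the list alone (median -1.06, camera adjusted p = 7.04e-05, and adjusted p = 0.25 with an estimated correlation). Cars, Wars and Nars fell 3.08-fold, 3.25-fold and 2.68-fold. Of 15 amino acid and nutrient transporter genes 8 fell and 1 rose (Slc7a11), equal over the list alone, with a median of -0.70 and Slc1a4, Slc6a9 and Slc38a2 lower by 3.85-fold, 4.61-fold and 2.43-fold. That list passed at an adjusted p of 0.0153 and had an adjusted p = 0.25 with an estimated correlation. In the unfolded protein response list 15 of 26 genes fell and 3 rose (15 and 4 adjusted over the list alone, median -0.70, or -0.46 with the length trend removed, camera adjusted p = 0.0102, and adjusted p = 0.217 with an estimated correlation). Herpud1, the chaperone gene Hspa5 and Derl3 fell by 2.34-fold, 2.13-fold and 2.35-fold. Each of these directions reverses under the normalized table's header, and the neutrophil markers fell in the same libraries (median -3.76).

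Transcripts of p53 target genes were higher in the count-table TCM libraries. Of 21 genes 19 rose, Sesn1 fell and Trp53 itself did not pass (log2 change 0.21), with equal counts adjusted over the list alone (median 1.86, camera adjusted p = 1.21e-08, and adjusted p = 0.0775 with an estimated correlation). Perp, Gtse1 and Zmat3 rose 15.5-fold, 12.9-fold and 7.19-fold, and Zmat3 reached 553 ± 25.4 CPM from 76.9 ± 4.72 CPM (SD, n = 3). Of 34 DNA replication genes 21 rose and 1 fell (Pold1), equal over the list alone (median 0.90, camera adjusted p = 2.36e-06, and adjusted p = 0.217 with an estimated correlation). Among them Rrm2 and Tyms rose 8.13-fold and 5.27-fold, while Mcm2, Mcm3, Mcm4, Mcm5, Mcm6 and Mcm7 of the replicative helicase did not pass. Of 34 mitosis genes 20 rose and none fell, equal over the list alone (median 0.53, or 0.30 with library totals alone, adjusted p = 0.00011, and adjusted p = 0.25 with an estimated correlation), with Birc5, Aurkb and Ccna2 up 5.30-fold, 4.27-fold and 2.99-fold. Of 18 replication histone genes 10 rose and 1 fell (12 and 1 adjusted over the list alone, median 1.40, adjusted p = 0.00839, and adjusted p = 0.473 with an estimated correlation), among them Hist1h1c, Hist1h4d and Hist1h2bc. Near-identical copies make the split of reads among histone genes uncertain. The normalized table's header reverses the directions of these 4 lists, and the neutrophil markers fell in the same libraries (median -3.76).

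The glycolysis, hypoxia and fatty acid oxidation lists were called higher in the count-table TCM libraries by camera at the preset correlation, and none kept its call with an estimated correlation. Of 19 glycolysis genes 16 rose and none fell, equal over the list alone (median 1.09, camera adjusted p = 2.58e-06, and adjusted p = 0.0775 with an estimated correlation). The enzyme genes Tpi1, Aldoc and Pgam1 rose 6.25-fold, 3.55-fold and 2.19-fold, and Tpi1 reached 784 ± 75.9 CPM from 125 ± 10.5 CPM (SD, n = 3). Tpi1 overlaps Spsb2. Of 24 hypoxia genes 18 rose, and Vegfa and Pfkfb4 fell (19 and 2 adjusted over the list alone, median 1.3, adjusted p = 1.00e-05, and adjusted p = 0.173 with an estimated correlation). Plod2, a collagen-modifying enzyme, rose 19.1-fold, the mitophagy receptor gene Bnip3 16.8-fold and Ak4 7.08-fold. In the fatty acid oxidation and PPAR list 16 of 23 genes rose and 4 fell, equal over the list alone (median 0.65, adjusted p = 0.00859, and adjusted p = 0.208 with an estimated correlation). Acads, Hilpda and Ppard rose 2.29-fold, 6.35-fold and 1.96-fold, and Hilpda is known as an inhibitor of lipid breakdown. Cpt1a, which admits fatty acids to mitochondria, was among the 4 that fell, at -0.57 on the log2 scale. Under the normalized table's header these lists fell instead. The neutrophil markers fell in the same count-table TCM libraries (median -3.76).

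The ribosomal protein and respiratory chain lists were called higher in the count-table TCM libraries by camera at the preset correlation, and neither kept its call with an estimated correlation. Of 49 ribosomal protein genes 30 rose and 1 fell (Rpl3), or 31 and 1 adjusted over the list alone (median 0.71, camera adjusted p = 1.73e-05, and adjusted p = 0.468 with an estimated correlation). Rps27, Rpl24 and Rps19 rose 1.84-fold, 1.93-fold and 1.95-fold. Of 44 oxidative phosphorylation genes 32 rose and none fell (33 and 0 adjusted over the list alone, median 0.79, adjusted p = 7.04e-05, and adjusted p = 0.468 with an estimated correlation). Sdhd, Ndufa9 and Atp5c1 rose 3.08-fold, 1.98-fold and 2.25-fold. Fold changes fell with transcript length across all genes, from a median of 0.44 in the fifth with the shortest transcripts to -0.36 in that with the longest. With this trend removed, a setting chosen after seeing the data, the ribosomal protein list no longer passed (median 0.27, adjusted p = 0.0851; 1.96e-08 to 0.0851 over the settings at the preset correlation), nor did Rps27 and Rpl24. The respiratory chain list still passed (median 0.40, adjusted p = 0.0184; 4.50e-07 to 0.0184 over the settings at the preset correlation). Of 14 metal response genes 8 rose and 2 fell, equal over the list alone (median 0.73, adjusted p = 0.0466), and the adjusted p = 0.227 with an estimated correlation. The iron exporter gene Slc40a1 fell 7.34-fold and Steap3 rose 2.59-fold, while Hamp, which encodes the iron hormone hepcidin, had 4 counts in FCM replicate 2 and 0 in the FCM libraries besides it, against 56, 70 and 89 counts in the count-table TCM libraries. The metal list did not pass with DESeq2's size factors (adjusted p = 0.0532), with a minimum of 50 counts (0.0663), without TCM replicate 1 (0.0673) or without TCM replicate 2 (0.0520), and its adjusted p ran from 0.0186 to 0.0673 over the settings at the preset correlation. The normalized table's header reverses these directions, and the neutrophil markers fell in the same libraries (median -3.76).

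**Figure D2:**
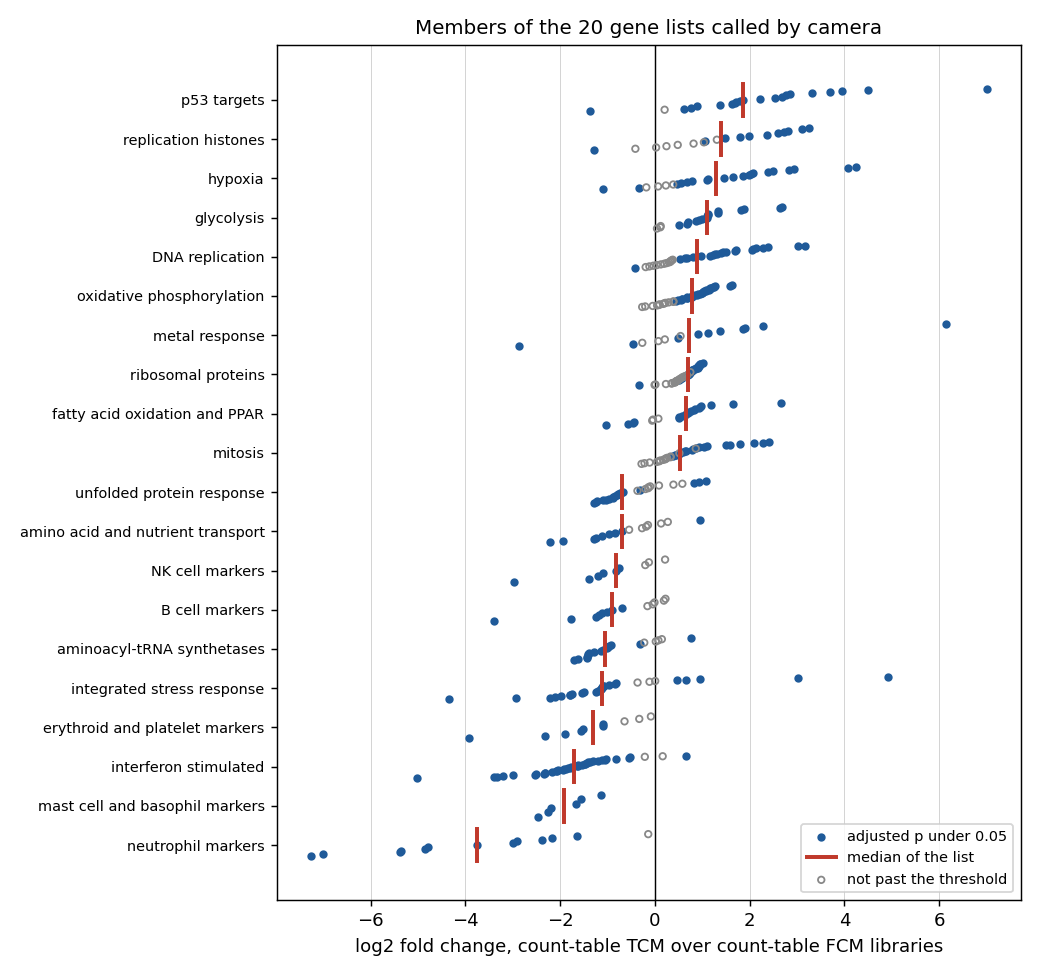
Log2 fold changes (count-table TCM over count-table FCM libraries) of the tested members of the 20 gene lists called by camera, 1 point per gene, filled where adjusted p was under 0.05, with each list's median as a bar. The list medians run from -3.76 for neutrophil markers to 1.86 for p53 targets, and the normalized table's header reverses the sign of every point.

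Markers of neutrophils, mast cells and basophils, B cells, erythroid cells and platelets, and NK cells were called lower as lists in the count-table TCM libraries by camera at the preset correlation, and none kept its call with an estimated correlation. Of 13 neutrophil markers 12 fell and Mmp8 did not pass, equal over the list alone (median -3.76, camera adjusted p = 1.52e-07, and adjusted p = 0.217 with an estimated correlation). Summed over the list, they made up 0.819% to 1.27% of the normalized counts of the count-table FCM libraries and 0.115% to 0.220% of those of the count-table TCM libraries. Mmp9 fell 13.6-fold from 152 ± 8.26 to 11.2 ± 1.04 CPM (SD, n = 3), and Elane fell 40.9-fold beside Ltf. All 6 mast cell and basophil markers fell, equal over the list alone (median -1.93, adjusted p = 0.00365), among them Gata2, Mcpt8 and Prss34 at 2.97-fold, 3.18-fold and 5.53-fold. That list had an adjusted p = 0.217 with an estimated correlation. Of 13 B cell markers 8 fell, equal over the list alone (median -0.91, adjusted p = 0.0155), with Fcrla down 10.5-fold, Cd79b 3.41-fold and Cd22 2.28-fold. The B cell list had an adjusted p = 0.217 with an estimated correlation. Of 10 erythroid and platelet markers 7 fell (8 adjusted over the list alone, median -1.31, adjusted p = 0.00672), including Slc4a1, Alas2 and the globin row Beta-s. It had an adjusted p = 0.208 with an estimated correlation and did not pass with a minimum of 50 counts (adjusted p = 0.0567; 0.000383 to 0.0567 over the settings at the preset correlation). Of 9 NK cell markers 6 fell, equal over the list alone (median -0.82, adjusted p = 0.0302), including Eomes, Fcgr3 and Itga2. Eomes also stands in the list of inhibitory receptors and exhaustion, and the call does not by itself show fewer NK cells. The NK list had an adjusted p = 0.217 with an estimated correlation and did not pass without TCM replicate 1 (adjusted p = 0.0586; 0.00321 to 0.0586 over the settings at the preset correlation). Under the normalized table's header all of these lists rose.

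The remaining marker lists did not pass camera. Of 15 T cell markers 3 rose and 4 fell, equal over the list alone, and the median (0.035, -0.16 to 0.078 over settings) and mean (0.0087) differed in sign from the test, which gave a downward direction (adjusted p = 0.924). Thy1 rose 2.75-fold, while Zap70 and Ptprc fell 1.81-fold and 1.93-fold. T cell markers summed to 0.220% to 0.237% of normalized counts in the count-table FCM libraries and 0.248% to 0.276% in the count-table TCM libraries. The TMM factors of the libraries ran from 0.840 to 1.18, so the percentages of such sums are not shares of the raw counts. In CPM these sums were 2199 to 2366 and 2478 to 2758, and Thy1 alone went from 336 to 923 CPM within them. The larger sum therefore does not show a larger share of T cells. Of 9 CD4 and regulatory T cell markers 2 rose and 2 fell, equal over the list alone (median 0.0055, -0.21 to 0.13 over settings, adjusted p = 0.845), with Foxp3 and Cd4 down 2.38-fold and 2.02-fold beside the rise of Ctla4. Summed over that list the share of normalized counts went from 0.0767% to 0.0826% in the count-table FCM to 0.135% to 0.14% in the count-table TCM libraries. Within that sum Ctla4 went from 46.5 to 375 CPM while Cd4 and Foxp3 fell, so the sum does not show a larger share of such cells. Of 10 antigen presentation genes 3 fell, equal over the list alone (median -0.27, -0.54 to -0.17 over settings, adjusted p = 0.201), namely H2-Ob, Ciita and H2-Oa. With the length trend removed that list passed at a median of -0.54 and an adjusted p of 0.0168 (up to 0.316 over the settings at the preset correlation), and with an estimated correlation, the trend left in, it had an adjusted p = 0.59. Of 19 macrophage and monocyte markers 5 rose and 11 fell, equal over the list alone (median -0.56, -0.91 to -0.52 over settings, adjusted p = 0.184). Lyz2 fell 12.7-fold from 414 ± 29.2 CPM (SD, n = 3) and Csf1r 3.73-fold, whereas Arg1, an arginine-degrading enzyme, rose 32.9-fold to 11.2 ± 1.59 CPM. Of 11 dendritic cell markers 4 rose and 5 fell, equal over the list alone (median -0.16, -0.44 to -0.038 over settings, adjusted p = 0.464). Batf3 rose 7.92-fold and Itgax fell 3.70-fold, and Clec9a had 3 counts over the count-table TCM libraries against 353, a ratio of 81.8 (95% exact counting interval 27.8 to 399). The summed dendritic cell markers went the other way from their median, from 0.105% to 0.132% of normalized counts in the count-table FCM to 0.16% to 0.191% in the count-table TCM libraries. Of 8 fibroblast and stroma markers 4 rose and 2 fell, equal over the list alone (median 0.42, -0.16 to 0.89 over settings, adjusted p = 0.464), with Pecam1 lower by 3.08-fold and Cav1 at 0.0534 ± 0.0212 and 1.24 ± 0.174 CPM. The epithelial and tumour cell list had 3 tested genes and was not tested as a list, and Muc1 rose 6.36-fold while Cdh1 and Epcam fell 7.98-fold and 2.02-fold. The mitochondrially encoded list had 0 tested genes. Every direction here reverses under the normalized table's header.

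Signalling and homing lists did not pass camera, although many of their genes passed edgeR's test, as did 58.8% of all genes tested. Of 24 NF-kB targets 13 rose and 5 fell, equal over the list alone (median 0.36, 0.15 to 0.39 over settings, adjusted p = 0.206), with Tnip3 up 3.45-fold and Tnfaip2 and the chemokine gene Cxcl10 down 6.63-fold and 4.10-fold. Of 23 STAT3 and STAT5 response genes 10 rose and 6 fell, equal over the list alone (median 0.29, 0.045 to 0.43 over settings, adjusted p = 0.243), with Il12rb2 up 6.14-fold and Il18rap down 3.98-fold. The median of that list was 0.095 without FCM replicate 1, 0.15 without TCM replicate 3 and 0.43 without TCM replicate 1. Of 20 TGF-beta response genes 7 rose and 2 fell (7 and 1 adjusted over the list alone, median 0.11, -0.097 to 0.22 over settings, adjusted p = 0.201), and Ldlrad4 and Pmepa1 rose 1.95-fold and 2.23-fold. Of 14 glucocorticoid response genes 3 rose and 8 fell (3 and 9 adjusted over the list alone, median -0.61, -0.83 to -0.50 over settings, adjusted p = 0.232), with Ddit4 up 8.17-fold and Il1r2 and Tgm2 down 3.37-fold and 2.23-fold. Of 18 cAMP response genes 3 rose and 6 fell (3 and 5 adjusted over the list alone, median -0.0056, -0.24 to 0.041 over settings, adjusted p = 0.845), with Crem and Dusp1 up 3.12-fold and 2.69-fold and Pde7b down 4.99-fold. Of 24 chemokine receptor and homing genes 5 rose and 12 fell, equal over the list alone (median -0.39, -0.60 to 0.015 over settings, adjusted p = 0.235), with Ccr8 up 2.30-fold and Ccr6 and Itgal down 3.64-fold and 2.06-fold. Of 23 apoptosis regulators 6 rose and 5 fell, equal over the list alone (median 0.20, -0.024 to 0.27 over settings, adjusted p = 0.464), with Bcl2l2 up 2.69-fold and Birc3 down 2.05-fold. The directions are those of the count table's header.

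Lipid, redox and protein turnover lists also did not pass. Of 24 cholesterol synthesis genes 3 rose and 11 fell (3 and 12 adjusted over the list alone, median -0.29, -0.50 to -0.24 over settings, adjusted p = 0.0863). Cyp51, a demethylase of the pathway, fell 2.25-fold. Of 20 fatty acid synthesis genes 10 rose and 4 fell (10 and 5 adjusted over the list alone, median 0.27, 0.066 to 0.34 over settings, adjusted p = 0.236), with Scd2, Lpin1 and Fads2 up 9.34-fold, 6.53-fold and 2.98-fold. Of 10 LXR targets 3 rose and 3 fell, equal over the list alone (median -0.090, -0.30 to -0.049 over settings, adjusted p = 0.845), with Pltp and Arl4c up 4.06-fold and 2.79-fold and Apoe down 6.20-fold. Of 24 NRF2 genes 12 rose and 4 fell, equal over the list alone (median 0.49, 0.26 to 0.53 over settings, adjusted p = 0.0855), with Gpx4 and Hmox1 up 3.31-fold and 2.58-fold and Mgst1 down 3.47-fold. Of 18 heat shock genes 3 rose and 9 fell, equal over the list alone (median -0.33, -0.54 to -0.29 over settings, adjusted p = 0.128), and Hsph1, Hspa8 and Hspa4 fell 3.87-fold, 2.43-fold and 1.99-fold. Of 33 ribosome biogenesis and MYC genes 5 rose and 15 fell (6 and 16 adjusted over the list alone, median -0.33, -0.55 to -0.27 over settings, adjusted p = 0.0991), with Dkc1, Wdr43 and Nop56 down 1.89-fold, 1.89-fold and 1.76-fold. Of 32 proteasome genes 15 rose and 8 fell (15 and 9 adjusted over the list alone, median 0.21, 0.0023 to 0.25 over settings, adjusted p = 0.281), with Psmb7 and Psma1 up 2.10-fold and 2.35-fold and Psmb10, an immunoproteasome subunit, down 1.94-fold. Of 34 lysosome and autophagy genes 13 rose and 5 fell (13 and 4 adjusted over the list alone, median 0.12, -0.078 to 0.20 over settings, adjusted p = 0.305), with Gla up 1.93-fold and Tfec and Gpnmb down 5.49-fold and 2.06-fold. The heat shock list passed with a minimum of 50 counts (adjusted p = 0.0229; up to 0.186 over the settings at the preset correlation). With the length trend removed the cholesterol synthesis list passed at 0.0454 (up to 0.138) and the ribosome biogenesis list at 0.0371 (up to 0.146), both also at the preset correlation. With an estimated correlation, all genes kept and the trend left in, the adjusted p of these 3 lists was 0.279, 0.253 and 0.468. Among the genes named by rule, Tpi1, Cyp51, Pltp, Aldh1l2, Wars, Ccna2, Dkc1, Wdr43, Nop56 and Ldlrad4 overlap the span of another tested gene, introns included. The same holds for Tgm2, Crem, Dusp1, Il12rb2, Slc6a9, Psmb7, Foxp3, Ciita, Csf1r and Alas2. Overlap of exons was not examined, so how far the exon counts of these genes are uncertain is not known. Under the normalized table's header the signs are opposite.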

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

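The settings without replicate number 1, without Rn45s, with the length trend removed and with the normalized table's header were chosen after the data were seen. The 4 gene counts and, DESeq2 aside, where camera was not run, the number of list calls (20) stayed within 1.5 times under every setting except library totals alone (2364 genes higher; the median of all genes moved by -0.21), an estimated correlation per list (0 lists called) and fry (40 lists, which tests another hypothesis). Leaving out 1 library gave 2878 to 4030 genes higher, 2818 to 4199 lower and 18 to 20 lists. Reads and header of the normalized table exchanged the counts (3726 higher, 3584 lower) and turned 12423 of 12423 signs. The replicate block (4509 higher, 4594 lower) changed no call of a named gene or list. Under the settings with the count table's header, 5595 to 7309 of the 7310 called genes were called again, each with the same sign.

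Medians of lists that did not pass camera changed sign as follows, and the cause was not tested. With DESeq2's size factors naive and memory was at 0.021 and cAMP response at 0.028. With library totals alone TCR early activation was at -0.0025, apoptosis regulators at -0.024, TGF-beta response at -0.10, lysosome and autophagy at -0.078, T cell markers at -0.16 and CD4 markers at -0.21. Without a filter CD4 markers were at -0.0050 and fibroblast markers at -0.16, and with a minimum of 50 counts, which drops genes, chemokine receptors were at 0.015. DESeq2 put naive and memory at 0.015 and fibroblast markers at -0.10. Without replicate number 1 T cell markers were at -0.046 and CD4 markers at -0.020. With the length trend removed naive and memory was at 0.24 and T cell markers at -0.16. Leaving out 1 library moved naive and memory between -0.16 and 0.067, cAMP response between -0.042 and 0.041, T cell markers between -0.028 and 0.078 and CD4 markers between -0.045 and 0.056. Beside CTL effector and STAT3 and STAT5 response, whose values stand in the report, other medians of such lists that moved by over 1.5 times without 1 library were early activation (0.13), LXR targets (-0.14) and dendritic markers (-0.040) without FCM replicate 1, and LXR targets (-0.18) and lysosome (0.20) without FCM replicate 2. Without FCM replicate 3 they were LXR targets (-0.049), lysosome (0.20) and dendritic markers (-0.30). Without TCM replicate 1 they were TGF-beta (0.18) and antigen presentation (-0.17), macrophage (-0.91) and dendritic markers (-0.083). Without TCM replicate 2 this was fibroblast markers (0.22), and without TCM replicate 3 TGF-beta (0.18), chemokine receptors (-0.24) and fibroblast markers (0.65). Of the 26 lists that were not called, medians of 23 moved by over 1.5 times with library totals alone and of 14 with the length trend removed, and their ranges stand in the report. With that trend removed the log2 changes of Ifng (0.84), Ccr8 (0.71), Ndufa9 (0.61), Psma1 (0.74), Hist1h2bc (0.59) and H2-Oa (-0.90) moved by over 1.5 times as well and still passed. Over the settings with camera at the preset correlation, 7 list results fell short of the threshold and 5 newly passed it. These counts leave out the removal of the GC content trend and any trend removal run together with the replicate block. Among the genes named by rule and the set from Csf3 to Tnfsf4 given below, 2 results fell short and 1 newly passed over these settings and DESeq2. Among all genes more calls were lost: without TCM replicate 2, edgeR called 5595 of the 7310 genes again. Depth limits genes with few counts: 1 count was worth up to 0.0583 CPM of the library total, before the scaling by TMM.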

Other observations

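The tests of the table headers and of the neutrophil markers, and the length test of each list by itself, were chosen only after the results were seen, and so were the genes of the next paragraph. Directions follow the count table's header and reverse under the normalized table's.

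Csf3, which encodes the neutrophil growth factor G-CSF, went from 0.119 ± 0.0295 CPM in the count-table FCM to 69.6 ± 13.8 CPM in the count-table TCM libraries (SD, n = 3), a log2 change of 9.10 ± 0.28 (SE). The chemokine genes Cxcl1, Cxcl2, Ccl7 and Ccl2 rose by 7.19, 4.35, 5.02 and 3.41 on the log2 scale, beside the 5.28 of Cxcl3. Csf3r, the receptor gene of G-CSF, fell 7.52-fold, and the neutrophil genes Cebpe and Cd177 fell 17.8-fold and 52.2-fold. Among lymphocyte genes, Xcl1, a chemokine gene of activated CD8 T cells, fell 10.1-fold from 1088 ± 242 to 108 ± 32.5 CPM, Crtam fell 7.23-fold and Il9r 17.6-fold, while the costimulatory ligand gene Tnfsf4 rose 10.3-fold. Adjusted p-values of edgeR's test for these 12 genes ran from 3.35e-07 to 2.01e-05.

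The opposite titles of the 2 tables leave open which libraries received TCM. Different libraries under shared titles are argued against by the ratio of matched columns, whose coefficient of variation was at most 1.79e-10. An exchange of the group names in 1 whole header predicts that each column matches the other group's column with the same number, and 6 of 6 did. Which header was exchanged cannot be told apart. The size factors of both tables differed by at most 3.54e-06, but they do not depend on the titles and could not favour either header.

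Neutrophil markers had a median of -3.76 in the count-table TCM libraries. An equal loss of all cells other than T cells is argued against, since the neutrophil median lay -2.85 from the lower of the B cell and antigen presentation medians. A smaller share of neutrophils with unchanged RNA content would change all markers equally if they came from neutrophils alone. The SD of the log2 changes over the 13 markers, 2.11, was 7.93 times their median standard error. Ltf lay at -7.26 and Mmp8 at -0.14. Whether other cells in these cultures also express some of the markers was not examined, so the unequal changes cannot decide on that explanation. No marker of the list stands in another list, its most abundant genes went from 3643 to 704 CPM (S100a9), 3553 to 84.8 CPM (Ngp) and 2779 to 887 CPM (S100a8), and no sort that would remove neutrophils is given. A change of neutrophil number, of state or of both may remain, together with the treatment itself and the open question of the headers.

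The ribosomal protein and respiratory chain lists had medians of 0.71 and 0.79. A GC content trend is argued against, since the larger median was 0.82 with that trend removed. With the length trend removed the larger median was 0.40, which leaves such a trend undecided for both lists together. The respiratory chain list passed camera at the preset correlation with the trend removed (adjusted p = 0.0184), but its median then no longer exceeded the SD over its members (0.46 before, 0.43 after). With an estimated correlation it did not pass even with the trend left in (adjusted p = 0.468). The ribosomal protein list lost its call (adjusted p = 0.0851, SD 0.27 before and 0.35 after) as its median fell to 0.27 and its spread grew, so a length trend and a change of these transcripts cannot be told apart for either list. With the replicate block and the length trend removed, the adjusted p-values at the preset correlation were 0.00567 for the respiratory chain and 0.0587 for ribosomal proteins, and an effect of the treatment stays open for both lists.

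The count of genes called by edgeR was 7310 for the real groups and at most 0 for the other splits of the 6 libraries into 3 and 3, and 1 of the 10 splits, the real one, gave as many. Genes with an unadjusted p under 0.05 numbered 7911 for the real groups and 1 to 684 for the other splits, and no other tool was run on the splits. With 10 splits the share cannot go under 0.05. Each other split puts libraries of both groups on each side, so the group difference widens the spread within sides. Few calls were possible there, and the contrast of 7310 with 0 decides nothing. The other splits that part all 3 pairs of replicate numbers called 0 genes, with 5 to 8 genes at an unadjusted p under 0.05.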
